A study of Mus musculus with 8 samples.

How the data were processed

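Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and adds sequencing adapters, in regulatory T (Treg) cells of mouse spleen and lymph nodes sorted from mixed bone marrow chimeras. The 8 libraries fall into 4 groups of 2: cTreg and eTreg cells, each wild type (WT) or deficient in Pggt1b. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 2 libraries of a group came from separate chimeras, so p-values measure the spread between these libraries, which may be partly technical.

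The deposited values are raw whole-number counts per peak, in 1 table of 79758 non-overlapping intervals, called sites here. Per the submitters' processing notes, the authors used Trimmomatic 0.36, Picard 2.9.4, SAMtools, MACS2 2.1.1 and bedtools, with the mouse build mm9 (NCBIM37). The aligner, the shift applied to read ends, the peak threshold, whether peaks were called on single or pooled libraries, and whether reads or fragments were counted are not given in the sources used here. A site list made from all groups would favour groups with deep libraries, and this could not be checked. Coordinates are given as in the deposited table, on mm9. Whether its starts count from 0 or 1 is not stated, so a start may be off by 1 base. All 8 columns of counts matched 1 sample title each.

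The gene table at hand belongs to another build, so no site was assigned to a gene. For that reason the 14 gene lists, the promoter and distal split, the 20 transcription factor motifs and the Pggt1b locus check, all fixed before the data were examined, were not run, and sites are named by position. No check of GC content was possible. No site list checks the genotype labels.

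Library totals were 12198749 and 12660311 counts for WT cTreg, 11194290 and 14974253 for WT eTreg, 8854687 and 7153991 for Pggt1b-deficient cTreg, and 2255214 and 1664702 for Pggt1b-deficient eTreg. In the Pggt1b-deficient eTreg libraries 12.5% and 16.39% of sites had no count, against 0.61% to 2.6% in the other 6. The common dispersion estimated within each group was 0.0072 for WT cTreg, 0.0102 for WT eTreg, 0.0111 for Pggt1b-deficient cTreg and 0.0437 for Pggt1b-deficient eTreg. Of counts from 1 to 10, 66.1% to 77.4% were even in each library, so many counts come in pairs, as when both reads of a fragment are counted. The chi-square per degree of freedom between the 2 libraries of a group was 2.07 to 2.3 with independent counts and 1.04 to 1.15 with every 2 counts as 1 observation. It was not used to judge agreement.

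Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, which left 75352 sites, TMM scaling, 1 model with a mean per group over all 8 libraries, and quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment within each comparison. A site was called at an adjusted p under 0.05. Standard errors of log2 fold changes were the absolute fold change over the square root of F. The 5 contrasts were eTreg against cTreg in each genotype, Pggt1b-deficient against WT in each subset, and their interaction. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33, so single values are given as mean ± SD without a test. Where a group had no count at a site, the fold was computed against a floor of 3 pairs, 6 counts over the group, and is a lower bound; with 1 to 6 counts, the ratio is given with its 95% Clopper-Pearson interval, with every 2 counts as 1 observation. Intervals and floors cover counting error only. The use of pairs was chosen after the data were seen. CPM values are counts scaled to a common library size after TMM scaling.

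Sites are named by a rule fixed before the data were examined: adjusted p under 0.05, a mean raw count of at least 20 over the libraries compared, no overlap in CPM between the 2 groups, and the 4 largest absolute fold changes in each direction. The interaction used all 8 libraries and no overlap rule. Sites, windows and contigs named outside this rule are said to have been chosen after their values were seen. The WT subset difference shares WT libraries with each genotype comparison, and these pairs were set beside 20 simulations without any effect. The interaction was set beside 10 simulations with the same subset difference in both genotypes. Comparisons that share Pggt1b-deficient libraries were not simulated in this way.

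The procedure was tested on simulated counts for 75352 sites with the dispersion of each group, with 100 sites changed 2-fold and 100 changed 4-fold. At 2-fold and 4-fold, edgeR recovered 65% and 98% of changed sites for eTreg against cTreg in WT, 58% and 96% for Pggt1b-deficient against WT in cTreg, 31% and 72% for the same in eTreg, 26% and 68% for eTreg against cTreg in Pggt1b-deficient cells, and 8% and 49% for the interaction. False calls numbered 3, 3, 28, 30 and 3 in that order, and 0, 1, 32, 29 and 12 when counts were simulated in pairs. Pggt1b-deficient against WT in eTreg had 28 false calls beside 31 and 72 recovered sites. The eTreg against cTreg comparison in Pggt1b-deficient cells had 30 beside 26 and 68. With pairs, the interaction had 12 beside 23 and 51. In each case false calls made up a larger share of calls than the adjusted p threshold allows. How far this carries over to the real data, with other numbers of changed sites, is not known. Limma-voom with weights per group made 10, 8, 10, 7 and 5 false calls, and 15, 3, 13, 5 and 9 with pairs. With independent counts it recovered 22% and 57% of changed sites for Pggt1b-deficient against WT in eTreg. It recovered 19% and 56% for eTreg against cTreg in Pggt1b-deficient cells, and 6% and 45% for the interaction. These shares are below those of edgeR, and the false calls again exceeded what the threshold allows. Its counts are given beside those of comparisons with Pggt1b-deficient eTreg libraries as a second method, not as a calibrated check.

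Alternatives fixed before the data were examined were the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), DESeq2 size factors, library totals and loess offsets in place of TMM, no filter or a mean count of at least 20, only the 4 libraries compared, a replicate block, a 2-fold minimum, leaving out X and Y, thinning to the smallest library and leaving out each library. Halved counts, group weights, leaving out both Pggt1b-deficient eTreg libraries, and another selection of subset sites were added after seeing the data.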

Results

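ATAC-seq counts at 79758 sites were compared between 2 subsets of mouse Treg cells, cTreg (central) and eTreg (effector) cells, from WT and Pggt1b-deficient donors of mixed bone marrow chimeras, with 2 libraries per group. In such chimeras marrow cells of more than 1 donor develop in 1 host. The labels do not say whether the compared WT and Pggt1b-deficient libraries came from the same hosts. Pggt1b encodes the catalytic subunit of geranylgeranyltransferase type I, an enzyme that attaches a lipid group to proteins such as small GTPases. The series title places the data in a study of protein prenylation and effector Treg cells. Sites were 1 to 4101 bp wide, with a median of 104 bp. Totals ran from 1664702 counts in a Pggt1b-deficient eTreg library to 14974253 in a WT eTreg library.

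By correlation of log2 CPM, the 2 libraries of a group resembled each other most in 3 of the 4 groups, but not in Pggt1b-deficient eTreg. Across sites, which are not independent replicates, log2 CPM correlated at r = 0.972 between the 2 WT cTreg libraries, 0.971 between the WT eTreg libraries, 0.953 between the Pggt1b-deficient cTreg libraries and 0.81 between the Pggt1b-deficient eTreg libraries. WT cTreg and Pggt1b-deficient cTreg libraries correlated at a mean of 0.949. Pggt1b-deficient eTreg libraries correlated at a mean of 0.848 with WT cTreg, 0.835 with WT eTreg and 0.834 with Pggt1b-deficient cTreg libraries, each above the value between the 2 Pggt1b-deficient eTreg libraries themselves. The first principal component, with 33.4% of the variance, separated eTreg from cTreg libraries of both genotypes. The second, with 29.1%, separated WT eTreg libraries (141.4 and 146.6) from Pggt1b-deficient eTreg libraries (-29.2 and -210.0) and also parted the latter. The third, with 23%, separated the 2 Pggt1b-deficient eTreg libraries from each other. The median count at tested sites was 8 and 6 in these 2 libraries, against 29 to 59 in the libraries of the other groups. Low counts add noise that lowers such correlations and parts libraries. These values therefore do not tell low depth from other differences between the 2 libraries.

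The first comparison asked how chromatin of eTreg and cTreg cells differs in the WT. Of 75352 sites tested, 10397 were more accessible in WT eTreg cells and 11202 were less accessible (edgeR quasi-likelihood test, adjusted p under 0.05, n = 2 and 2). The median log2 fold change was 1.17 at the eTreg-higher sites and -1.31 at the eTreg-lower sites. Among wide sites, more were gained than lost: of 2578 sites over 800 bp, 32.4% were higher and 8.6% lower in eTreg cells, whereas of 34580 sites of up to 100 bp, 8.6% were higher and 11.3% lower. Neighbouring called sites within 10 kb changed in the same direction in 85.9% of 8294 pairs, against 50.1% when directions were shuffled. The permutation p was 1e-04, the smallest that 10000 permutations can give. The shuffle treats sites as independent, although near sites may be parts of the same open region. Its p-value does not measure the spread between libraries.

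The site with the largest rise in WT eTreg cells under the naming rule, chr3:10682190-10682247, had no count in WT cTreg libraries and 4.22 ± 3.35 CPM (SD, n = 2) in WT eTreg libraries, at least 19.1-fold higher (edgeR adjusted p = 2.47e-07). chr4:117751266-117751426 and chrX:149409110-149409196 also had no count in WT cTreg libraries and were at least 14.9-fold and 14.4-fold higher. At chr5:74872805-74872923, counts rose from 2 in WT cTreg to 258 in WT eTreg libraries, a 127-fold ratio (95% interval 22.3 to 5040). In the other direction, chr13:28787113-28787168 fell from 4.07 ± 1.31 CPM to no count, at least 17.3-fold lower (edgeR adjusted p = 6.46e-09). chr17:52308317-52308417 fell 90.7-fold (95% interval 9.25 to 93900), chr1:191644221-191644292 fell 45.9-fold (7.82 to 1850) and chr6:127933805-127933924 fell 41.3-fold (7.0 to 1670).

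Changed sites were dense in some regions, here 200 kb windows that were chosen after their values were seen. In WT eTreg cells, 21 of 54 sites rose and none fell at 47.8 to 48 Mb of chromosome X, and 17 of 30 rose and none fell at 12.6 to 12.8 Mb of chromosome 10. At 51.8 to 52 Mb of chromosome 17, 32 of 46 sites fell and 1 rose, with a median log2 fold change of -2.05 over all 46. At 96 to 96.2 Mb of chromosome 10, 36 of 74 sites fell and 1 rose. The number of called sites dropped to 12945 and 12756 without WT cTreg replicate 1 or 2, and to 14213 and 13094 without WT eTreg replicate 1 or 2. DESeq2 called 13976 sites, and 13258 of the edgeR calls changed at least 2-fold.

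The next comparison asked whether loss of Pggt1b changes accessibility in cTreg cells. It gave 399 sites higher and 1270 sites lower in Pggt1b-deficient cTreg cells (edgeR, adjusted p under 0.05, n = 2 and 2). These were the fewest calls of the 4 pairwise comparisons in this model, but with only the 4 compared libraries in the model they numbered 3480, against 3174 for eTreg against cTreg in Pggt1b-deficient cells. The 10397 WT eTreg-higher sites had a median log2 fold change of -0.19 in this comparison, and the 11202 WT eTreg-lower sites one of 0.04. Of the 1270 lower sites, 746 were WT eTreg-higher sites, where independent lists would share 175.2, and 87 were WT eTreg-lower sites. Both comparisons use the WT cTreg libraries, which on its own ties their fold changes positively: the simulated covariance was 0.042, or 0.073 with counts in pairs, and the observed one -0.085.

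The largest rise in Pggt1b-deficient cTreg cells was at chr18:46407338-46407406, a 68 bp site that went from 0.399 ± 0.0047 CPM in WT to 15.6 ± 3.14 CPM in Pggt1b-deficient cTreg cells, a log2 fold change of 5.25 ± 0.40 (SE; edgeR adjusted p = 1.3e-11). The same site rose in Pggt1b-deficient eTreg cells, by 4.76 ± 0.43 (edgeR adjusted p = 3.44e-10). All 4 WT libraries lay between 0.371 and 0.747 CPM and all 4 Pggt1b-deficient libraries between 13.4 and 18.4 CPM. Pggt1b also lies on chromosome 18, but the position of this site relative to the gene was not analysed here. A DNA difference carried with the targeted allele is therefore possible, so the rise need not be one in accessibility. Other rises were at chr4:58978618-58978753 (36.4-fold from 4 counts, 95% interval 9.54 to 309, edgeR adjusted p = 7.17e-06, range over alternatives 9.75e-11 to 0.0564), chr5:108356026-108356170 (log2 fold change 3.10 ± 0.31) and chr18:42186011-42186068 (2.97 ± 0.43).

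**Figure D1:**
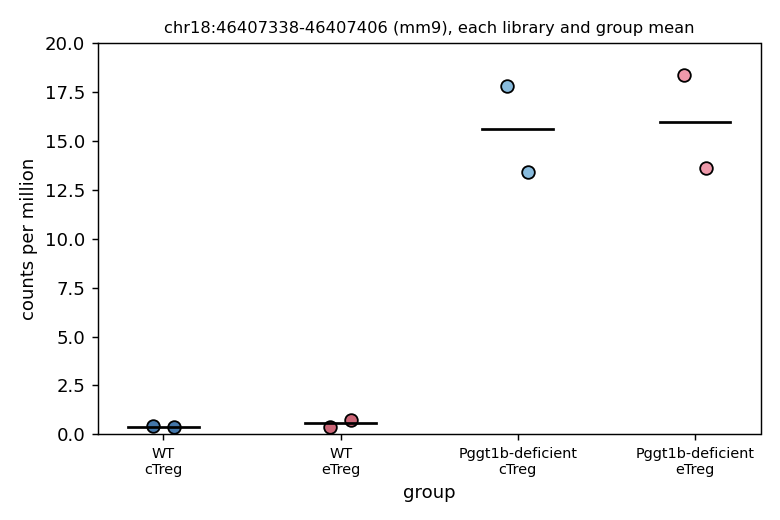
Counts at the site chr18:46407338-46407406 in CPM (vertical axis) in each of the 8 libraries, by group (horizontal axis). Points are libraries and lines are group means; the WT libraries lie between 0.371 and 0.747 and the Pggt1b-deficient libraries between 13.4 and 18.4.

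The largest falls in Pggt1b-deficient cTreg cells were at chr1:93041576-93041628 (27.1-fold lower, 95% interval 4.61 to 1100, with 2 counts left), chr1:58449344-58449702 (log2 fold change -3.54 ± 0.49), chr8:54957682-54957878 (-3.35 ± 0.49) and chr1:58954519-58954607 (10.3-fold lower, 3.33 to 51.8, with 6 counts left). The first of these rested on WT cTreg replicate 1, with 5.72 CPM against 1.03 CPM in replicate 2. The same site had 5.1 CPM in WT eTreg replicate 1 and 0.272 CPM in WT eTreg replicate 2. Its edgeR adjusted p was 0.0185, but 0.579 without WT cTreg replicate 1 and 0.259 without Pggt1b-deficient cTreg replicate 1 (range over all alternatives 0.000367 to 0.579). chr1:58954519-58954607 had an edgeR adjusted p of 0.00143, but 0.0923 without Pggt1b-deficient cTreg replicate 1 (range 5.8e-05 to 0.0923). The other 2 falls had an edgeR adjusted p of 1.54e-05 at chr1:58449344-58449702 and 3.21e-05 at chr8:54957682-54957878, but 0.105 and 0.0565 with counts thinned to the smallest library (ranges 1.02e-08 to 0.105 and 4.72e-06 to 0.0565).

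The count for cTreg cells moved with the libraries in the model. It was 378 and 459 without WT cTreg replicate 1 or 2, 426 and 833 without Pggt1b-deficient cTreg replicate 1 or 2, and 3109 and 3112 without Pggt1b-deficient eTreg replicate 1 or 2. The latter are in neither group compared, but their removal changed the estimate of spread and the sites tested, 78317 and 78098. Without both it was 3163, with 1185 higher and 1978 lower.

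The third comparison asked whether loss of Pggt1b changes accessibility in eTreg cells. Of 75352 sites, 3511 were higher and 4843 lower in Pggt1b-deficient eTreg cells (edgeR, adjusted p under 0.05, n = 2 and 2). On simulated counts, edgeR made more false calls in this comparison than that threshold allows. The changes ran against the WT subset difference: the WT eTreg-higher sites had a median log2 fold change of -0.69 (-0.59 with loess offsets), and the WT eTreg-lower sites one of 0.58. Among the calls, 3026 of the eTreg-higher sites fell and 62 rose, where independent lists would share 668.2 and 484.4. Of the eTreg-lower sites, 2248 rose and 83 fell. Both comparisons use the WT eTreg libraries, so part of this opposition comes from shared error. The covariance of their fold changes was -0.64, against -0.043 in simulations without effect, or -0.071 with counts in pairs.

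At 12.6 to 12.8 Mb of chromosome 10, where 17 of 30 sites were higher in WT eTreg cells, 13 were lower in Pggt1b-deficient than in WT eTreg cells and none higher. At 51.8 to 52 Mb of chromosome 17, where 32 of 46 sites were lower in WT eTreg cells, 12 were higher in the Pggt1b-deficient cells and none lower. At 142.8 to 143 Mb of chromosome 6, 15 of 51 sites were higher and 1 lower. These windows were chosen after their values were seen.

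4 sites named by rule had 213 to 314 counts over the WT eTreg libraries and none in Pggt1b-deficient eTreg libraries. chr2:136357765-136358070 was at least 8.03-fold lower (edgeR adjusted p = 5.51e-06), chr14:123378177-123378309 at least 6.47-fold, chr1:93839253-93839374 at least 6.16-fold and chr17:78703533-78703784 at least 5.45-fold. The site chr12:52988996-52989062 rose from 2.68 ± 0.14 to 31.6 ± 8.62 CPM, a log2 fold change of 3.57 ± 0.31 (edgeR adjusted p = 1.94e-10). The other 3 named rises differed widely between the Pggt1b-deficient eTreg libraries. chr17:65208313-65208351 had 8.52 and 42.1 CPM there, chr2:93612372-93612489 had 39 and 7.7 CPM, and chr2:112347778-112347939 had 57.9 and 305 CPM.

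Limma-voom with group weights, which allows for the larger spread of the Pggt1b-deficient eTreg libraries, called 2562 sites higher and 2024 lower, so the balance of directions was not stable: 42% of the edgeR calls were higher, against 55.9% with group weights and 52.7% with DESeq2. The count was 5386 and 4569 without WT eTreg replicate 1 or 2 and 5092 without Pggt1b-deficient eTreg replicate 1.

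The last pairwise comparison asked whether Pggt1b-deficient eTreg and cTreg cells differ as the WT subsets do. In Pggt1b-deficient cells 3461 sites were higher and 3409 lower in eTreg than in cTreg cells (edgeR, adjusted p under 0.05, n = 2 and 2). Here too, edgeR made more false calls on simulated counts than that threshold allows. The direction was shared with the WT: 2249 of the higher sites were WT eTreg-higher and 41 WT eTreg-lower, where independent lists would share 477.5 and 514.5. Of the lower sites, 2152 were WT eTreg-lower and 33 WT eTreg-higher. These comparisons share no library.

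The size of the difference was smaller. WT eTreg-higher sites had a median log2 fold change of 0.52 in Pggt1b-deficient cells against 1.17 in the WT, and WT eTreg-lower sites had -0.63 against -1.31. These medians moved by at most 0.04 when sites with a group at no count were set at their bounds. The WT medians are raised by the selection of these sites in the WT. Over all sites the slope of the Pggt1b-deficient on the WT difference was 0.513, with r = 0.36 across sites. Error in the WT difference lowers this slope, so it does not give the retained share of the difference. Within the WT, the replicate 2 difference on the replicate 1 difference had a slope of 0.757 at full depth.

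The share of counts gives the same order. WT eTreg-higher sites held 18.29 ± 0.09% of counts in WT cTreg (SD, n = 2), 27.0 ± 0.18% in WT eTreg, 17.24 ± 0.41% in Pggt1b-deficient cTreg and 21.78 ± 0.40% in Pggt1b-deficient eTreg libraries. WT eTreg-lower sites held 17.74 ± 0.09%, 9.99 ± 0.01%, 18.35 ± 0.57% and 13.7 ± 0.67%. The gap between subsets in Pggt1b-deficient cells was thus 52.1% of the WT gap at eTreg-higher and 60.0% at eTreg-lower sites. With sites selected from WT replicate 1 alone and the WT gap taken from replicate 2, it was 38.6% and 68.2%, a selection made after seeing the data.

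**Figure D2:**
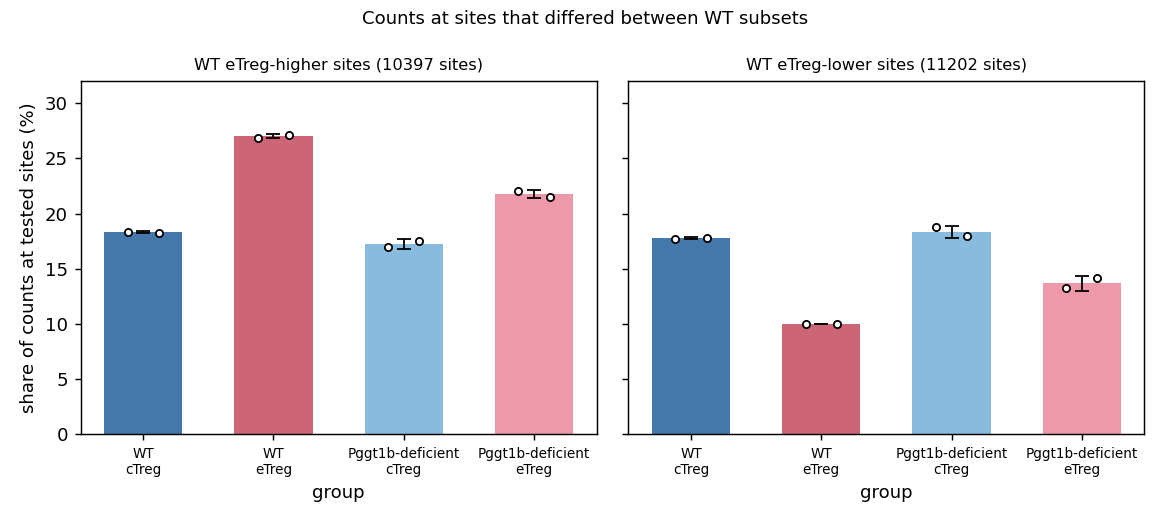
Share of counts at tested sites (vertical axis, percent) held by the 10397 sites higher and the 11202 sites lower in WT eTreg than in WT cTreg cells, in each group (horizontal axis). Bars are means, whiskers the SD and circles the 2 libraries; Pggt1b-deficient eTreg libraries lie between the WT eTreg and the cTreg libraries.

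**Figure D3:**
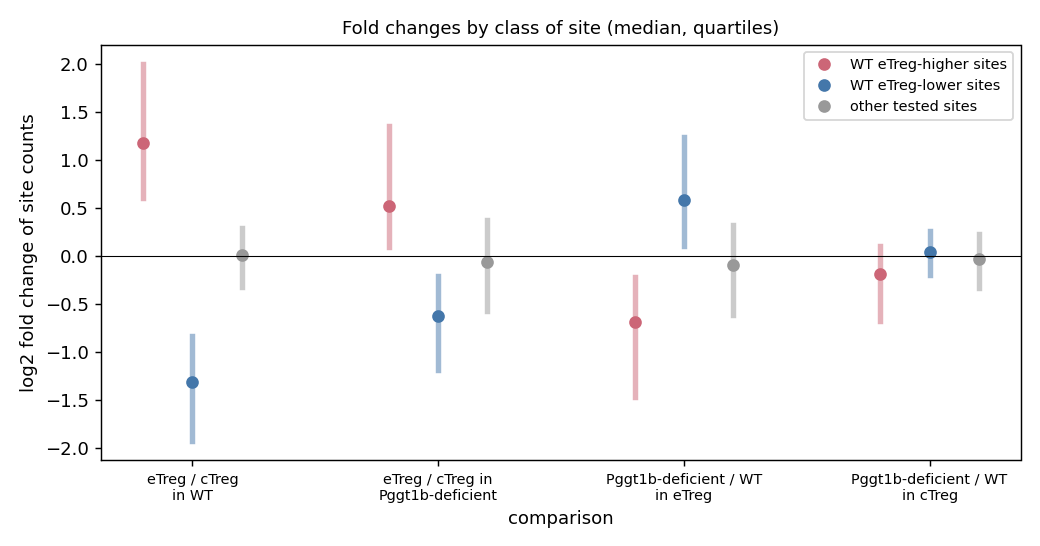
Log2 fold changes (vertical axis) in 4 comparisons (horizontal axis) at WT eTreg-higher sites, WT eTreg-lower sites and other tested sites. Dots are medians over sites and bars span the quartiles; the median of eTreg-higher sites is 1.17 in the WT and 0.52 in Pggt1b-deficient cells.

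Sites named in this comparison include chr1:20733926-20733995, which had 0.362 ± 0.122 CPM in Pggt1b-deficient cTreg and 18.4 ± 12.6 CPM in Pggt1b-deficient eTreg libraries (52.9-fold from 6 counts, 95% interval 16.8 to 268, edgeR adjusted p = 2.05e-08). chr17:65208313-65208351, chr7:99330456-99330625 and chr13:113973556-113973637 rose by 4.71 ± 0.58, 4.27 ± 0.47 and 4.17 ± 0.48 on the log2 scale. The site chr17:51875191-51875331 had 89 counts in Pggt1b-deficient cTreg libraries and none in Pggt1b-deficient eTreg libraries, at least 3.6-fold lower. chr15:7989973-7990089, chr7:89005153-89005319 and chr5:117960969-117961060 were at least 3.84-fold, 3.64-fold and 3.51-fold lower. Group weights called 2188 sites higher and 912 lower, so 70.6% of its calls were higher against 50.4% with edgeR. The count was 3161 without Pggt1b-deficient cTreg replicate 1 and 3342 without Pggt1b-deficient eTreg replicate 1.

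The effect of Pggt1b loss was shared in part between subsets. Of the 399 sites higher in Pggt1b-deficient cTreg cells, 181 were also higher in Pggt1b-deficient eTreg cells and 2 were lower. Of the 1270 lower sites, 718 were also lower and 8 were higher. Independent lists would share 18.6 higher and 81.6 lower sites. Across sites the fold changes of the 2 comparisons, which share no library, correlated at r = 0.221.

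The interaction, which tests whether the effect of Pggt1b loss differs between eTreg and cTreg cells, was called at 721 sites with a higher and 418 with a lower log2 fold change in eTreg cells (edgeR, adjusted p under 0.05, all 8 libraries). Of the 721, 563 were WT eTreg-lower sites, and of the 418, 268 were WT eTreg-higher sites. The interaction contains the WT subset difference with the opposite sign, so shared error favours these pairings. In 10 simulations with the same subset difference in both genotypes, counts in pairs and 1 dispersion per group, edgeR called 0 interaction sites. However, these simulations leave out differences in spread between sites. With 0 calls, they also cannot show how shared error would distribute false calls over the WT classes. The test on simulated pairs with changed sites gave 12 false interaction calls, more than the threshold allows beside 23 and 51 sites recovered. Group weights called 663 and 152 sites, 81.3% of them higher against 63.3% with edgeR. The count was 484, 382, 589 and 582 without WT cTreg replicate 1 or 2 and WT eTreg replicate 1 or 2, 578 without Pggt1b-deficient cTreg replicate 2 and 2035 without Pggt1b-deficient eTreg replicate 2.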

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

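In this part, the tests of whole pairs of counts, of background reads, of cTreg cells in the sort and of a DNA difference were chosen only after the results were seen; the test of depth was written beforehand.

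The effect of Pggt1b loss differed between eTreg and cTreg cells at 1139 sites by the interaction test (edgeR, adjusted p under 0.05). Among the sites named by rule, the effect was higher in eTreg cells at chr13:28882207-28882425 (edgeR adjusted p = 0.0213), chr7:125403443-125403563 (0.00244), chr3:141914013-141914098 (0.0012) and chr8:10980053-10980230 (0.00406). At the last of these, WT cells had 4.91 ± 0.34 CPM in cTreg and 0.389 ± 0.026 in eTreg libraries, and Pggt1b-deficient cells 3.42 ± 0.24 and 3.8 ± 0.34. The effect was lower in eTreg cells at chr6:65415536-65415704 (edgeR adjusted p = 0.0174), chr16:45093478-45093625 (0.00542), chr10:45355139-45355230 (0.0412) and chr2:136357765-136358070 (0.00503). All 4 of these had no count in Pggt1b-deficient eTreg libraries. The call at chr13:28882207-28882425 rested on 14 counts in Pggt1b-deficient eTreg replicate 2; without that library its log2 fold change was -3.69 (edgeR adjusted p = 0.731; range over alternatives 0.00017 to 0.731). Over the alternatives the adjusted p (edgeR, DESeq2 or limma) ran from 0.0305 to 0.377 at chr10:45355139-45355230, 0.0135 to 0.132 at chr6:65415536-65415704 and 0.00315 to 0.0736 at chr16:45093478-45093625, each highest without Pggt1b-deficient cTreg replicate 2. It ran from 0.00111 to 0.164 at chr7:125403443-125403563 (0.0655 without Pggt1b-deficient eTreg replicate 1), 0.000299 to 0.236 at chr3:141914013-141914098 and 0.00197 to 0.0535 at chr2:136357765-136358070, each highest with counts thinned to the smallest library. Of the 8 sites, chr8:10980053-10980230 alone stayed past the threshold in each alternative that gave it a value, with an adjusted p up to 0.0355. It had a value in 19 alternatives, against 20 at chr3:141914013-141914098 and chr2:136357765-136358070 and 21 at chr7:125403443-125403563. It was thus not tested in all of them, and this does not show it to be more stable than those sites.

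A pattern across sites is a smaller eTreg to cTreg difference in Pggt1b-deficient cells. Lower depth does not account for it: WT replicate 2 libraries thinned to the totals of the Pggt1b-deficient libraries kept slopes of 0.708 and 0.686, or 0.733 and 0.708 when whole pairs of counts were thinned, on the difference between the WT replicate 1 libraries, whereas the Pggt1b-deficient libraries gave 0.485 and 0.368. Even background reads would lower the share of counts at the strongest 10% of sites without a WT subset difference. That share was 60.9% in both Pggt1b-deficient eTreg libraries against 58.5% to 59.8% in the other 6. This goes against such reads acting alone, but another difference between libraries could hide them. However, the weakest 10% held 0.817% and 0.83% in Pggt1b-deficient eTreg libraries against 0.6% and 0.675% in WT eTreg libraries. They held 0.784% and 0.873% in Pggt1b-deficient cTreg and 0.751% and 0.666% in WT cTreg libraries. The measure first used was the share of the weakest over that of the strongest 10%, relative to the WT eTreg mean. It was 1.246 and 1.267 in Pggt1b-deficient eTreg, 1.23 and 1.368 in Pggt1b-deficient cTreg and 1.194 and 1.046 in WT cTreg libraries. It was replaced after its values were seen. These shares therefore do not decide whether background reads contribute. Admixed cTreg cells in the eTreg sort cannot be told apart from a change within cells: of the sites called between genotypes in eTreg cells, 12.7% were called beyond Pggt1b-deficient cTreg levels in the same direction, but both comparisons share the Pggt1b-deficient eTreg libraries and the share that mixing alone would give is not known. An effect of Pggt1b loss on the eTreg program stays open as well.

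The site on chromosome 18 that separates the genotypes may reflect a DNA difference carried with the targeted allele. Of 44 sites changed at least 4-fold in the same direction in both subsets, 2 lay within 1 Mb of its position. These were the site itself, chr18:46407338-46407406 (higher), and chr18:46173003-46173149 (lower). A 2 Mb window on chromosome 7 held 3, so the counts are too few to decide. A count of changed neighbours also cannot tell whether the site belongs to the targeted allele. The genome sequence and the design of the allele were not used here, and an effect of Pggt1b loss on these sites was not tested separately.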

How the results depend on the processing

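Halved counts, group weights, the model without both Pggt1b-deficient eTreg libraries and the replicate 1 selection were chosen after the data were seen. The number of called sites and the balance of directions depend on the setting. Comparisons are lettered: A is WT eTreg against WT cTreg (21599 sites in the main model), B Pggt1b-deficient against WT in cTreg (1669), C the same in eTreg (8354), D Pggt1b-deficient eTreg against cTreg (6870) and E the interaction (1139). Counts within 1.5 times are left out, and causes were not tested unless named. DESeq2 called 13976, 867 and 747 in A, B and E. Limma-voom called 2599, 5018 and 3314 in B to D, and group weights 2866, 4586 and 3100. A 2-fold minimum left 13258, 736 and 4491 in A, B and D. Thinned to the smallest library, fewer counts gave 5287, 88, 3512, 3099 and 154 in A to E. The 4 libraries compared gave 3480, 5340 and 3174 in B to D, and B had 3163 without both Pggt1b-deficient eTreg libraries. Halved counts gave 3067 in B and 4233 in D. Over all alternatives the share of higher calls ran from 43.2% to 50.9% in A, 11.5% (without WT cTreg replicate 2) to 43.6% (the 4 libraries compared) in B, 39.1% to 55.9% in C, 46.4% to 70.6% in D and 52.8% to 92.9% (thinned) in E. Leaving out 1 library, so that a group keeps 1 that is assumed to vary like the others, gave 12756 to 26040, 378 to 3112, 4569 to 8133, 3161 to 7317 and 382 to 2035. DESeq2 size factors, library totals, loess offsets and both filters kept all 5 counts within 1.5 times. The slope of the Pggt1b-deficient on the WT difference was 0.424 to 0.588 and the correlation of the Pggt1b effects 0.152 to 0.223 with 1 library left out; that correlation was 0.303 at WT-called sites, 0.206 with loess offsets and 0.233 with halved counts. The Pggt1b-deficient gap at eTreg-higher sites, 52.1% of the WT gap, was 39.5% with sites from WT replicate 1 and 38.6% with the WT gap from replicate 2. The interaction at chr13:28882207-28882425 turned from 4.49 to -3.69 without Pggt1b-deficient eTreg replicate 2 and was 8.35 without WT eTreg replicate 1. The labels do not say whether libraries with the same replicate number share a chimera. Deviations between replicates correlated at -0.016 to 0.057 across groups, but counting error lowers such values, so they cannot settle it. With the replicate block the counts were 20212, 1569, 7781, 6341 and 1041. Alternatives for gene lists, promoters and motifs were not run, since no site was assigned to a gene. In Pggt1b-deficient eTreg libraries depth limits the calls: a site without counts there is not shown to be closed.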

Other observations

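All values and tests in this part were chosen after the data were seen.

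Of the 44 sites changed at least 4-fold in both subsets, 6 were higher and 38 lower in Pggt1b-deficient cells. The higher sites include 3 on chromosome 7 that lie within 2 kb of each other, among them chr7:111439326-111439455, with log2 fold changes of 2.86 ± 0.28 in cTreg and 2.68 ± 0.33 in eTreg cells (edgeR adjusted p = 6.72e-09 and 3.51e-07). Among the lower sites, chr10:44541462-44541730 had -2.11 ± 0.37 in cTreg and -2.13 ± 0.27 in eTreg cells, and chr4:97527618-97527825 had -2.38 ± 0.45 and -2.45 ± 0.31. At 144.8 to 145 Mb of chromosome 4, 6 of 72 sites were lower in Pggt1b-deficient cTreg cells and 14 in Pggt1b-deficient eTreg cells, and none was higher in either.

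Of 2578 sites over 800 bp, 18.2% were higher and 4.3% lower in Pggt1b-deficient eTreg than in Pggt1b-deficient cTreg cells. Pggt1b-deficient eTreg cells lay above both WT eTreg and Pggt1b-deficient cTreg cells at 479 sites and below both at 578. Both comparisons use the Pggt1b-deficient eTreg libraries, so shared error favours such joint calls. The numbers expected without any effect were not simulated.

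Sites on chromosomes 11 and 19 took a higher share of counts in Pggt1b-deficient libraries. Chromosome 11 held 4.413% and 4.373% of counts in the Pggt1b-deficient cTreg libraries against 4.0% and 3.889% in the WT cTreg libraries, and 4.275% and 4.159% against 3.824% and 3.839% in eTreg libraries. Chromosome 19 held 2.071% and 2.077% against 1.889% and 1.883% in cTreg libraries, and 2.187% and 2.063% against 1.932% and 1.972% in eTreg libraries. The median log2 fold change between genotypes was 0.14 on chromosome 11 and 0.11 on chromosome 19 in cTreg cells, and 0.06 and 0.04 in eTreg cells. All 4 medians stayed above 0 with DESeq2 size factors, library totals and loess offsets. These scalings do not correct for GC content, which could not be checked, so the shares are not shown to result from Pggt1b loss. Chromosome 9 also held a higher share in the Pggt1b-deficient than in the WT libraries of each subset. Its medians were -0.008 in cTreg and -0.025 in eTreg cells. Those of chromosomes 15 and 17 were 0.042 and 0.038 in cTreg cells, but -0.054 and -0.02 in eTreg cells.

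5 sites on the unplaced contigs NT_166473 and NT_166476 held 0.116% and 0.0837% of counts in the Pggt1b-deficient eTreg libraries (95% Clopper-Pearson intervals 0.11 to 0.123 and 0.0776 to 0.0902, with every 2 counts as 1 observation), against 0.0147% and 0.0152% in WT eTreg libraries. Reads from repeated DNA in low-yield libraries are a candidate explanation: the shallower Pggt1b-deficient cTreg library had 2.03 times the share of the deeper one (95% interval 1.85 to 2.24), but of the 2 Pggt1b-deficient eTreg libraries the deeper had the higher share. An effect of Pggt1b loss may also contribute, but the deeper Pggt1b-deficient cTreg library had 0.92 times the share of the higher WT cTreg library (95% interval 0.84 to 1.02, which includes no difference). Neither can be told apart with 2 libraries per group.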
